A study of Homo sapiens with 117 samples.

How the data were processed

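Platelet-poor plasma miRNAs were measured by real-time PCR in 36 cases with type 1 MI and 81 controls, all from people living with HIV. Per the labels' protocols, RNA was extracted with a serum and plasma miRNA kit and amplicons were detected with the EvaGreen dye. The deposited table holds non-normalized Cq values, which the authors' table gives per assay and sample and which lie on a log2 scale where a lower value means more template. The instrument, reverse transcription, preamplification, Cq threshold, cycle limit and any filter are not given in the sources used here. A value of 0 was read as not detected, since no other value lay below 4.06 and none above 21.0. That reading and the log2 scale were taken from the values, and a PCR efficiency below 100% would make each log2 difference an overstatement of the true one.

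Groups were taken from the sample titles and conditions in the labels. Of 187 assay entries, 6 repeated the name of another, and the Cq values of each pair were averaged, which left 181 miRNAs, and 8 assays were never detected. Pairs of samples were checked for identity: 0 pairs were identical, and the smallest root mean square difference between samples was 0.503 cycles. Depth was taken as the number of miRNAs detected per sample (5 to 152) and the mean Cq (10.8 to 19.2). Samples with few miRNAs contributed few values, so n is given per miRNA. The file names no genome build, and miRNA names were used as given. Neighbouring miRNA genes were taken from a RefSeq gene table of assembly GRCh38.p14, without coordinates.

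Since fewer than 10 miRNAs were detected in every sample, each sample was normalized to the mean Cq of the 18 miRNAs detected in at least 95% of samples (global mean), over the values present. Log2 relative abundance was the negative of the Cq after subtracting that mean. The 61 miRNAs detected in at least 80% of samples were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, missing values left out), with Benjamini-Hochberg adjustment and a threshold of 0.05. Detection was compared by two-sided Fisher's exact tests for miRNAs detected in 10% to 90% of samples. Sample quality was compared by two-sided permutation tests of the difference in means with 100000 resamples.

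The 20 miRNA lists were fixed before the data were examined and cover muscle, blood cells, endothelium, smooth muscle, liver, inflammation, HIV-1 RNA, lipids, coronary events, hypoxia, epithelium, brain, the let-7, miR-17-92 and miR-30 families, the 14q32 cluster and reference miRNAs. Lists with at least 3 tested members were tested with limma's cameraPR on the moderated statistics, with a preset correlation of 0.01. cameraPR took the place of the planned camera, which accepts no missing values. camera with an estimated correlation, and fry, were run on values in which a missing value was set to the miRNA's mean over all samples. The miRNAs named were, by a rule fixed in advance, those past the threshold or the 20 with the lowest p if fewer passed, the 3 with the lowest p for detection, all measured muscle, liver and coronary-event miRNAs, the haemolysis pair, and the 2 members of each other list with the lowest p. The miRNAs named for assay sets or Cq behaviour (miR-7-2-3p, miR-21-5p, miR-30a-5p, miR-30d-5p, miR-1825, miR-126-5p, miR-218-2-3p, miR-34a-5p, miR-320b) or technical SDs (miR-92a-1-5p) were chosen after their values were seen. The remaining tested lymphocyte miRNA, miR-29a-3p, was also named after its value was seen. Names without an arm, such as miR-1, miR-133a, miR-134 and let-7c, were matched to the usual arm.

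Alternatives covered the normalization, the filter on detection, the treatment of missing values, the test, covariates (mean Cq, haemolysis index, platelet index), and a block on the replicate numbers. Alternatives on the assay sets, on samples with fewer than 50 miRNAs, on reference assays whose slope on the mean Cq of the others was under 0.5 and on an additive fit were added after seeing the data. The procedure was tested on simulated data made from these samples with permuted group labels, in 50 runs with 15 of 61 miRNAs changed. For the case-control comparison, 28% of changes of 0.5, 76.4% of 1 and 98.8% of 2 on the log2 scale were called, with a mean of 0.12 unchanged miRNAs called per run. With the mean Cq as a covariate these shares were 52.8%, 92.0% and 99.2%, with 0.28 unchanged miRNAs called.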

Results

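MicroRNAs (miRNAs), the short RNAs that repress messenger RNAs, were measured by real-time PCR with the EvaGreen dye in platelet-poor plasma from people living with HIV. Cases had a type 1 myocardial infarction (MI), the kind caused by rupture or erosion of a coronary plaque, and controls did not. The table held 36 cases and 81 controls, and the labels number the samples without saying whether each came from a different person, so p-values measure the spread between these samples. In all, 187 assays measured 181 miRNAs, of which 6 were measured by a pair of assays each. The quantification cycle (Cq), which falls by about 1 for each doubling of the template, ranged from 4.06 to 21.0 with a median of 17.0, and 47.2% of the 21879 values were not detected. The number of miRNAs detected per sample ranged from 5 to 152, with a median of 96, and 4 cases and 10 controls had fewer than 50.

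Markers of red cell and platelet RNA, and the amount of RNA, differed between the groups by less than the spread between samples. The mean Cq of 18 reference miRNAs was 14.4 ± 1.93 (SD, n = 36) in cases and 14.4 ± 1.95 (SD, n = 81) in controls, with a two-sided permutation p of 0.987. Over all samples it spanned 8.39 cycles. That span is not a fold range of template, since the mean was taken over the values present and includes assays that hardly followed the amount of RNA. Cases had 97.8 ± 34.7 miRNAs detected (SD, n = 36) and controls 94.6 ± 32.8 (SD, n = 81; permutation p = 0.638). The haemolysis index, the Cq of miR-23a-3p minus that of the red cell miRNA miR-451a, was -3.39 ± 1.73 in 34 cases and -3.44 ± 1.77 in 79 controls (permutation p = 0.886). It ran from -7.34 to 2.23 with a median of -3.67, so 0 samples lay above 7, the usual mark of haemolysis. Whether that mark holds for these assays was not tested, so the count does not show the samples to be free of haemolysis. The platelet index, the mean relative abundance of 8 platelet miRNAs, was -0.243 ± 1.58 in 36 cases and -0.116 ± 1.18 in 80 controls (permutation p = 0.629). Technical SDs from the repeated assays were 0.243 cycles for miR-150-5p, 0.215 for miR-7-2-3p and 0.479 for miR-92a-1-5p. The corresponding SDs over samples were higher, at 2.11, 2.10 and 0.970. For miR-7-2-3p that SD includes a jump between 2 assay sets described below, and within set 1 it was 0.473. The 2 assays of a pair gave the same detection call in 82.1% (miR-206) to 100% (miR-150-5p) of samples.

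The first comparison asked whether plasma miRNA abundance differed between cases and controls. The highest-ranked miRNAs were 3 members of the miR-125 family, relatives of the worm lin-4 miRNA that act in blood cell development and inflammatory signalling, with mean abundances 1.38 to 1.42 times those of controls. miR-125a-3p was 0.51 higher on the log2 scale (SE 0.20, 34 cases against 77 controls), miR-125a-5p 0.50 higher (SE 0.20, 34 against 78) and miR-125b-5p 0.46 higher (SE 0.18, 32 against 69). Their values lay above the control median in 22 of 34, 25 of 34 and 23 of 32 cases. With limma and Benjamini-Hochberg adjustment over 61 miRNAs, 0 were called at 0.05: the unadjusted p was 0.0118, 0.0124 and 0.0125 for these 3, and the adjusted p was 0.253 for each. They were the 3 miRNAs with an unadjusted p under 0.05, where 3.05 are expected by chance.

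When each sample's mean Cq was a covariate, limma called the same 3 miRNAs, and all 3 rose in cases. The differences were 0.50 (SE 0.14, adjusted p = 0.0219) for miR-125a-3p, 0.47 (SE 0.14, adjusted p = 0.0314) for miR-125a-5p and 0.51 (SE 0.15, adjusted p = 0.0219) for miR-125b-5p. The standard errors were smaller than without the covariate. The mean difference of the 3 miRNAs depended on the normalization: without the covariate it was 0.49 with the global mean, 0.34 with the median Cq, 0.35 with quantile normalization and 0.23 with miR-103a-3p and miR-484, and limma called 0 miRNAs with each. With the global mean of the 14 reference miRNAs whose Cq followed the others, a normalization added after seeing the data, it was 0.46 and limma called the same 3 (lowest adjusted p in the case-control miRNA abundance test = 0.0425). Unadjusted p-values under 0.05 were also reached by miR-148b-3p (0.39, p = 0.0197), miR-148a-3p, a regulator of the low-density lipoprotein receptor (0.38, p = 0.0239), and miR-139-5p (0.28, p = 0.04), none of which passed adjustment.

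**Figure D1:**
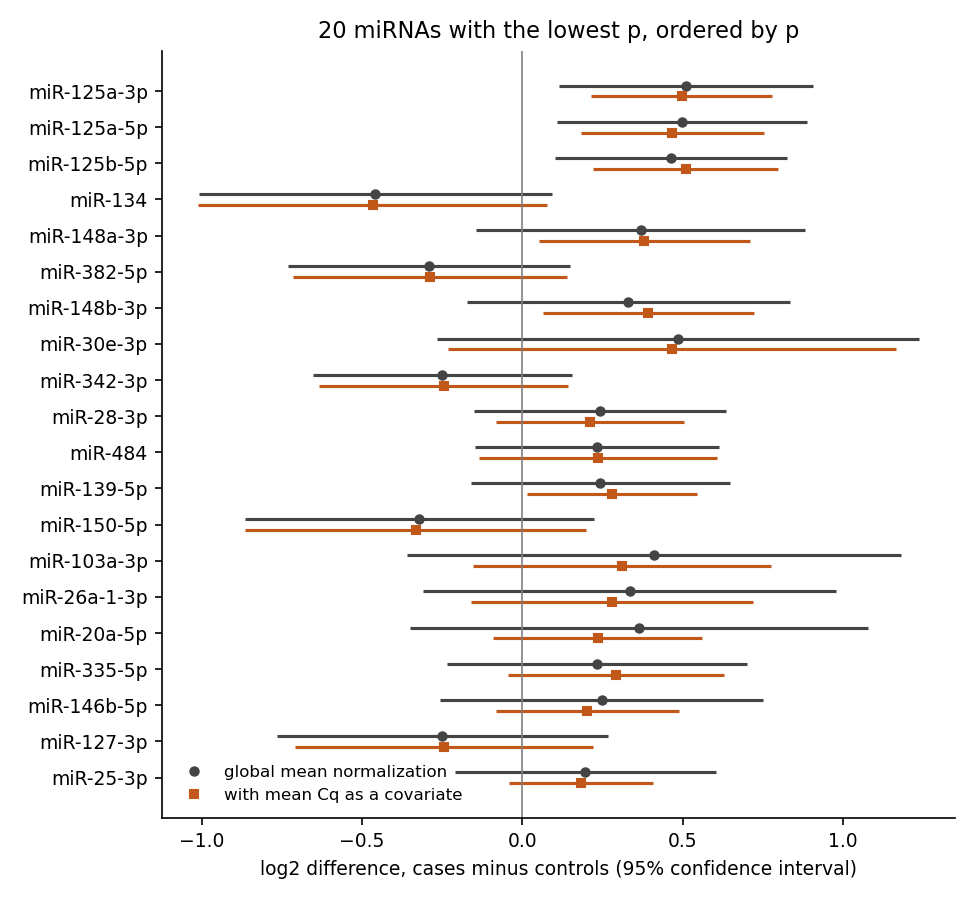
Log2 differences in relative abundance, cases minus controls, with 95% confidence intervals, for the 20 miRNAs with the lowest p, after normalization to the global mean (circles) and with the mean Cq of each sample as a covariate (squares). The intervals of miR-125a-3p, miR-125a-5p and miR-125b-5p lie above 0 in both fits, and adjustment over 61 miRNAs leaves them past the threshold in the second fit.

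The samples were divided into 2 assay sets by the Cq of miR-7-2-3p, a split that was found in the data and is absent from the labels: 88 samples (29 cases, 59 controls) lay below 13 and 29 samples (7 cases, 22 controls) above. Set 2 was itself split, with 20 samples between 13.5 and 15.1 and 9 between 17.5 and 18.1, and was analysed as 1 set. With all 3 levels as a covariate, limma also called 0 miRNAs (3 at an unadjusted p under 0.05). In set 1, the mean of the 3 miR-125 miRNAs was 0.60 higher in cases (SE 0.19, 26 cases against 48 controls), and in set 2 it was 0.38 higher (SE 0.37, 6 against 21). The difference in set 2 was within 2 standard errors of 0, and a limma test of whether case-control differences depended on the set called 0 of 61 miRNAs (0 at an unadjusted p under 0.05, lowest adjusted p = 0.964).

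**Figure D2:**
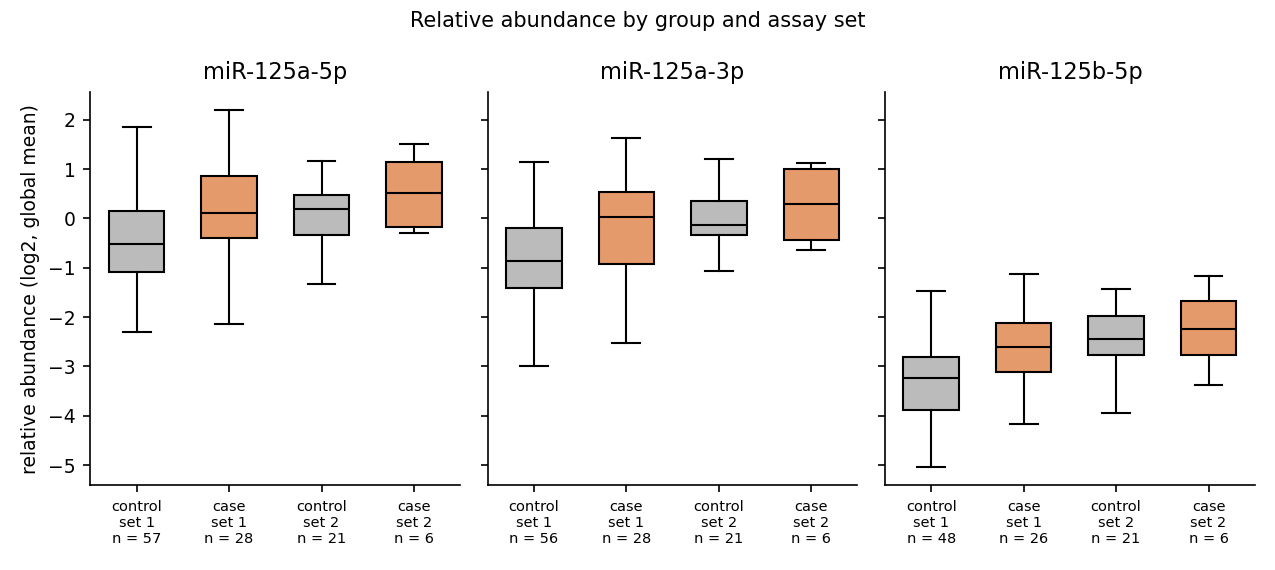
Relative abundance (log2, against the global mean) of miR-125a-5p, miR-125a-3p and miR-125b-5p by group and assay set. Boxes span the quartiles, lines mark medians, whiskers reach the most extreme samples that are not outliers, and outlying samples are not drawn. Case medians lie above control medians in both sets for each miRNA. In set 2 the 6 cases lie on both sides of the control median, so their median is imprecise. The mean difference of the 3 was 0.60 in set 1 (SE 0.19) and 0.38 in set 2 (SE 0.37).

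The other miRNAs among the 20 with the lowest p did not pass the test, and each had an adjusted p of 0.876 without the covariate. Lower values in cases were seen for miR-134 (-0.46, SE 0.28), miR-382-5p (-0.29, SE 0.22) and miR-127-3p (-0.25, SE 0.26), which come from the imprinted cluster at 14q32. They were also seen for miR-150-5p (-0.32, SE 0.27) and miR-342-3p (-0.25, SE 0.20), which are abundant in lymphocytes. Higher values were seen for miR-148a-3p (0.37), miR-148b-3p (0.33), miR-30e-3p (0.48), miR-28-3p (0.24), miR-484 (0.23), miR-139-5p (0.24), miR-103a-3p (0.41), miR-26a-1-3p (0.33), miR-20a-5p (0.36), miR-335-5p (0.23), miR-146b-5p (0.25) and miR-25-3p (0.20). Over all 61 miRNAs the median difference was 0.15 with 44 positive, but it was 0.01 with 31 positive after normalization to the median Cq, 0.05 with 38 positive after quantile normalization and -0.15 with 9 positive after normalization to miR-103a-3p and miR-484. The 95% confidence interval reached a median of 0.551 to either side of the estimate, a 1.47-fold difference.

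Muscle, liver and coronary-event miRNAs gave no difference that passed the test (limma adjusted p of 0.876 or more for each one tested for abundance). Of the muscle-enriched miRNAs, miR-133b differed by -0.24 (SE 0.39, 36 cases against 76 controls), and its Cq did not follow the amount of RNA (slope 0.031 on the mean Cq of the other reference miRNAs). The other muscle miRNAs were compared by detection: miR-1 was detected in 21 of 36 cases and 49 of 81 controls (two-sided Fisher's exact test, p = 0.841), miR-133a in 3 and 9 (p = 0.753) and miR-206 in 15 and 34 (p = 1). Of the liver miRNAs, miR-122-5p, the most abundant miRNA of hepatocytes, differed by 0.04 (SE 0.36, 35 against 77), miR-192-5p was detected in 27 cases and 58 controls (p = 0.823) and miR-194-5p in 18 and 37 (p = 0.692). Of the miRNAs used in earlier plasma panels of coronary events, the lymphocyte miRNA miR-150-5p had the largest difference (-0.32, SE 0.27). Then came miR-126-3p from endothelium and platelets at 0.13 (SE 0.34) and miR-140-3p at -0.08 (SE 0.24). miR-223-3p of myeloid cells and platelets differed by 0.07 (SE 0.38) and miR-197-3p by 0.03 (SE 0.23). miR-132-3p was detected in 20 cases and 41 controls (p = 0.691) and miR-186-5p in 26 and 58 (p = 1). The haemolysis pair differed by 0.20 (SE 0.26) for miR-451a and 0.05 (SE 0.33) for miR-23a-3p.

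Of 12 miRNA lists fixed in advance that had at least 3 tested members, 1 was called as lower in cases relative to the other miRNAs: the imprinted 14q32 cluster, also called the DLK1-DIO3 locus, whose miRNAs are expressed from the maternal chromosome. Its 3 tested members, miR-134, miR-382-5p and miR-127-3p, were all negative, with a median of -0.29 and an adjusted p of 0.00258 with limma's cameraPR and a preset correlation. The call was lost with an estimated correlation of 0.536 between members (adjusted p = 0.0805). limma's fry called 0 lists, with an unadjusted p of 0.118 for this one, and 0 of its members were called when adjusted over the list alone. The mean of the 3 members was -0.42 in assay set 1 (SE 0.25, 23 cases against 45 controls) and 0.15 in set 2 (SE 0.39, 6 against 21). Over the 36 cases and the controls that share their numbers, the list median was positive (0.14) and the call was lost.

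The other lists did not pass the test, and their directions are relative to the global mean, since 44 of all 61 miRNAs were positive with it and 9 after normalization to miR-103a-3p and miR-484. Of blood cell lists, the lymphocyte list had 3 of 3 tested members negative (2 of 3 without normalization), with a median of -0.25. Its cameraPR adjusted p was 0.0631. The members were miR-150-5p, miR-342-3p and miR-29a-3p, which lay near 0 (-0.007, SE 0.27). The adjusted p was 0.277 for camera with an estimated correlation and 0.59 for fry. In assay set 2 alone, 1 of the 3 was negative and the median was 0.01. Members of the red blood cell list, of which miR-25-3p (0.20) and miR-92a-3p (0.19) had the lowest p, were positive in 5 of 5 with a median of 0.20 (adjusted p = 0.463 with the global mean), but in 0 of 5 after normalization to miR-103a-3p and miR-484. The platelet list had 6 of 8 positive, including miR-28-3p (0.24) and miR-328-3p (0.14), and a median of 0.10 (adjusted p = 0.689). The myeloid list, which holds miR-125a-5p and miR-146b-5p, had 4 of 5 positive and a median of 0.25 (adjusted p = 0.421). For the platelet list the median and the direction of the test differed in sign, since the test sets members against the other miRNAs, and the same held for the endothelial list (3 of 5 positive, median 0.04, adjusted p = 0.421) and the coronary event panel (3 of 5 positive, median 0.03, adjusted p = 0.421). The endothelial list includes miR-126-3p and miR-100-5p (-0.17, SE 0.33).

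The inflammatory signalling list, with miR-125b-5p and miR-146b-5p, had 3 of 4 positive (median 0.25), the list of miRNAs described as binding HIV-1 RNA had 2 of 5 positive (median -0.01), and the let-7 family had 2 of 5 positive (median -0.02), with let-7e-5p at 0.06 and let-7c at -0.06. The miR-17-92 family, with miR-20a-5p and miR-92a-3p, had 5 of 5 positive (median 0.24), but 0 of 5 after normalization to miR-103a-3p and miR-484. Each of these 4 lists had an adjusted p of 0.421. The lipid metabolism list, with miR-148a-3p and miR-27b-3p (0.21, SE 0.30), had 4 of 4 positive (median 0.14, adjusted p = 0.694). Adjusted over the list alone, miR-125b-5p was called in the vascular smooth muscle list (limma adjusted p = 0.0249) and in the inflammatory signalling list (0.0498), and 0 miRNAs were called in the others. The remaining lists had fewer than 3 tested members and were not tested: vascular smooth muscle and plasma reference with 2 each, cardiac muscle and hepatocyte with 1 each, and hypoxia, epithelial, brain and miR-30 with 0.

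**Figure D3:**
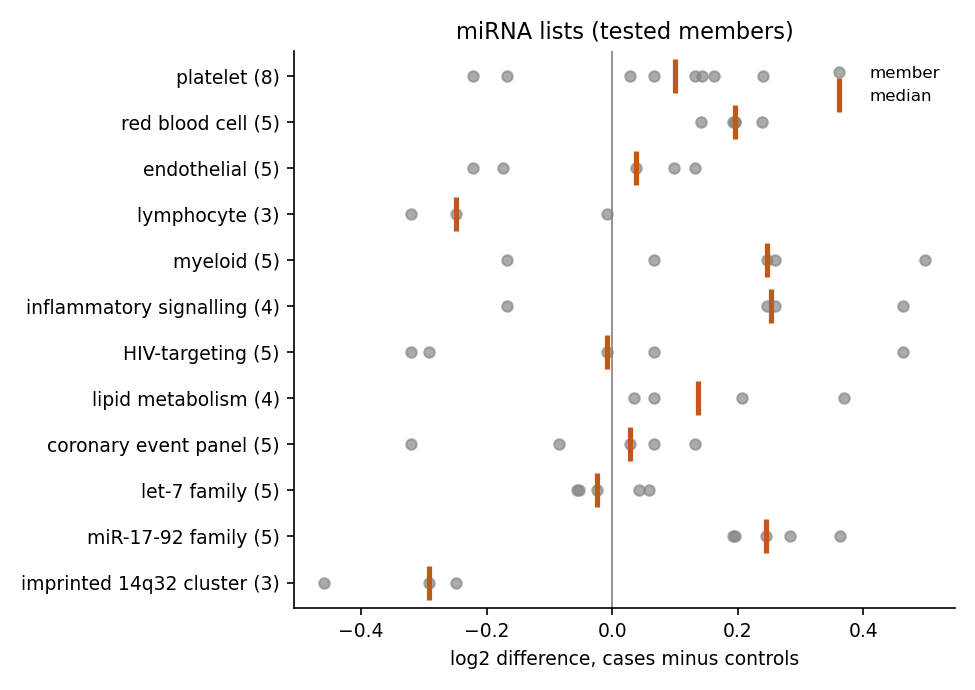
Log2 differences, cases minus controls, of the tested members (grey points) of the 12 tested miRNA lists, with the list median as a bar and the number of members in parentheses. The 3 members of the imprinted 14q32 cluster lie below 0 with a median of -0.29. The 3 lymphocyte members have a median of -0.25, and 1 of them, miR-29a-3p, lies near 0 (-0.007).

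The second comparison asked whether any miRNA was detected more often in one group. miR-1291, miR-146a-3p, the passenger arm of an NF-kB-induced miRNA, and miR-7-1-3p ranked first, and each was detected in 17 of 36 cases (47.2%) and 23 of 81 controls (28.4%; two-sided Fisher's exact test, p = 0.0586 each). Of 121 miRNAs detected in 10% to 90% of samples, 0 were called, 0 had an unadjusted p under 0.05 and 75 were detected in a higher share of cases. With logistic regression on group and mean Cq, 0 were called, 5 had an unadjusted p under 0.05 and the lowest adjusted p was 0.33. All 3 first-ranked miRNAs were detected in 40 of 88 samples of assay set 1 and in 0 of 29 of set 2, and the case-control detection rate test within set 1 gave 0.111 as the lowest p of any miRNA.

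The assay sets differed in which miRNAs were detected. miR-30a-5p was detected in 81 of 88 samples of set 1 and 0 of 29 of set 2, miR-30d-5p in 80 and 0, and miR-1825 in 83 and 0. miR-126-5p was detected in 88 of 88 and 8 of 29, while miR-126-3p, the other arm of the same precursor, was detected in 84 and 27. Within set 2, miR-126-5p was detected in 8 of the 20 samples with the lower Cq of miR-7-2-3p and 0 of the 9 with the higher, and miR-126-3p in 19 and 8. miR-218-2-3p was detected in 3 of 88 and 18 of 29. Of 181 miRNAs compared by Fisher's exact test with Benjamini-Hochberg adjustment, 52 were detected less often and 21 more often in set 2. Cases and controls were spread over the sets in similar shares (two-sided Fisher's exact test, p = 0.488).

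**Figure D4:**
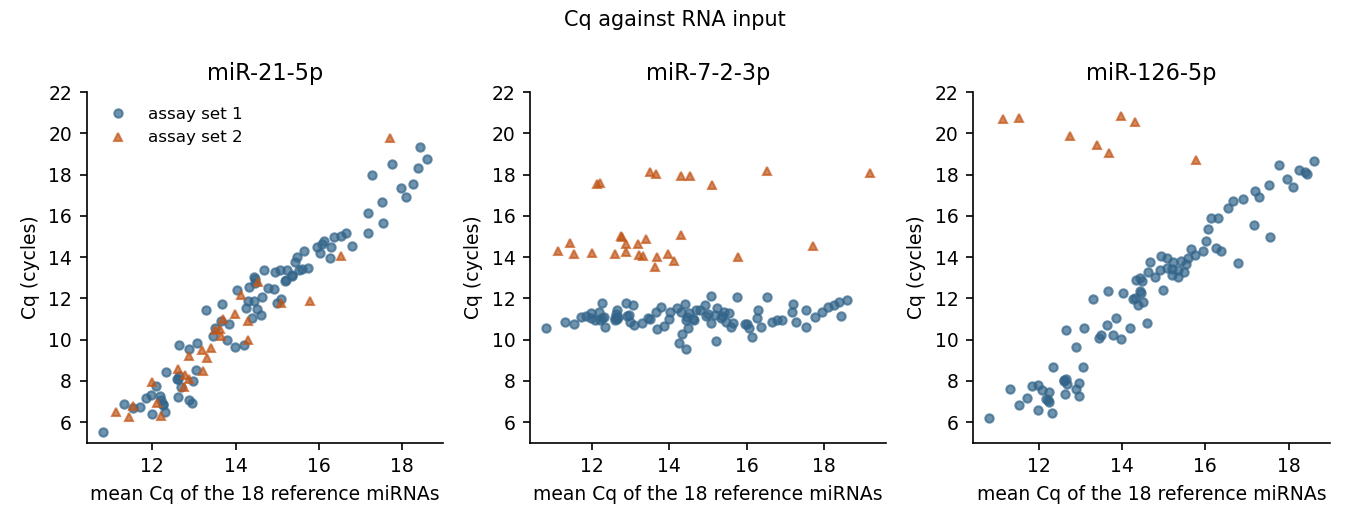
Cq (cycles) of miR-21-5p, miR-7-2-3p and miR-126-5p against the mean Cq of the 18 reference miRNAs in each sample where it was detected, with circles for assay set 1 and triangles for set 2. miR-21-5p follows 1 line in both sets, miR-7-2-3p stays between 9.53 and 12.1 in set 1 and in set 2 lies either between 13.5 and 15.1 (20 samples) or between 17.5 and 18.1 (9 samples), and miR-126-5p was detected in 8 of 29 samples of set 2.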

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

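Tests on the assay sets, on samples with fewer than 50 miRNAs detected, on the reference assays used, on the additive fit and, for lists, on the mean Cq and the shared numbers were chosen only after the results were seen. The count of miRNAs called by limma in the case-control miRNA abundance test was 0 in 23 of 29 alternatives and 3 in the other 6, always miR-125a-3p, miR-125a-5p and miR-125b-5p. The planned ones of the 6 were the mean Cq as a covariate (3 called, lowest adjusted p = 0.0219) and the platelet index as a covariate (3, 0.0382). Those added were assay set and mean Cq as covariates (3, 0.00798), assay set 1 alone with mean Cq (3, 0.0029), samples with at least 50 miRNAs with mean Cq (3, 0.00714) and the global mean without 4 input-independent assays (3, 0.0425). The differences of these 3 miRNAs were positive in 28 of 28 alternatives, from 0.22 to 0.59 for miR-125a-5p, 0.27 to 0.62 for miR-125a-3p and 0.20 to 0.67 for miR-125b-5p, with adjusted p from 0.0029 to 0.98. Several of these, such as the looser detection filters, the Wilcoxon test, robust eBayes and the haemolysis limit, leave the estimate unchanged and are not separate checks of its sign. The alternative on miRNAs detected in every sample tested 2 miRNAs and none of this family. The mean Cq as a covariate lowered the median residual SD over miRNAs from 1.35 to 0.875. The platelet index may not be a separate check from the mean Cq, and how closely it follows it was not tested. In set 1, slopes of its members on the mean Cq of input-responsive reference miRNAs ran from 0.726 (miR-328-3p) to 1.63 (miR-223-3p). The index also holds miR-126-5p, which was detected in 8 of 29 samples of set 2, so it is not a clean measure of platelet RNA. In the list tests the count called was 1, the 14q32 cluster, and it was again called without normalization, after normalization to miR-103a-3p and miR-484, and with the haemolysis index, mean Cq or assay set as a covariate (adjusted p from 0.00101 to 0.0271). The count was 0 with the estimated correlation, 0 with the replicate block and 0 over the shared numbers without the block. The cause of the last was not tested. Detection counts and sample quality kept their side of the threshold in every alternative run.

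Among 34 named miRNAs, 102 of 949 alternative values had the other sign, in 27 miRNAs. Of these, 2 lay beyond 2 SE, both under the replicate block: the log2 difference of miR-140-3p was 0.48 and the log2 difference of miR-100-5p was 0.69, neither past adjustment; the cause was not tested. The block called 0 miRNAs (7 at an unadjusted p under 0.05, lowest adjusted p = 0.194), and the same samples without it 0 (4, 0.169). The 36 shared numbers were not taken to pair the samples, because the correlation of deviations was above 0.1 for 22 of them and not for all. Its median was 0.156, against -0.0156 for differently numbered samples, and 2 cases correlated best with their own number. Spike-in and small nucleolar RNA normalization were not run, the haemolysis limit removed 0 samples, and normalization to miR-103a-3p and miR-484 rests on 95 samples with both.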

Other observations

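The tests of the assay sets, of Cq behaviour, of splits other than the count of miRNAs called without a covariate, and of explanations for the miR-125 and 14q32 results were chosen only after the result was seen; the fits with the mean Cq as a covariate and the estimated correlation were planned as alternatives. The slopes of Cq on the mean Cq of the other reference miRNAs differed between miRNAs: miR-223-3p of myeloid cells and platelets had a slope of 2.07, miR-23a-3p 1.84 and miR-21-5p 1.81, against 0.622 for the liver miRNA miR-122-5p and 0.821 for the lymphocyte miRNA miR-150-5p. That mean includes assays that hardly followed the amount of RNA, which raises the slopes of the others.

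The miR-125 family was higher in cases by a mean of 0.49 (SE 0.18), and 0.54 (SE 0.14) with the mean Cq as a covariate. Over all 36 cases and 81 controls the mean Cq differed by -0.00618 cycles. That near balance argues against a difference in RNA amount between the full groups, and the fit adds no separate test of it. The 2 estimates used the 32 cases and 69 controls with all 3 miRNAs detected, where the balance of the mean Cq was not tested. With the mean Cq as a covariate, the mean of the family was 0.66 (SE 0.15) within assay set 1, so a difference between sets does not account for it there. Within set 2 it was 0.30 (SE 0.34), which is too imprecise to tell. With the same covariate, the mean over both sets exceeded that of the genomic neighbours let-7e-5p, let-7c and miR-100-5p by 0.57 (SE 0.16). The size of the family difference depends on the choice of normalization, which may account for part of it. After normalization to miR-103a-3p and miR-484 the mean was 0.24 (SE 0.17, over the 29 cases and 65 controls with all 3 detected). Relative to the median of all 61 miRNAs it was 0.34 with the global mean and 0.39 with that pair. Subtracting 1 value per sample moves all miRNAs by about the same amount. This relative value could therefore hardly change (0.34 without normalization) and does not test the choice of normalization. With the global mean it was 0.44 in set 1 and 0.09 in set 2. Carry-over into the miR-125a-5p assay does not account for the call of miR-125a-3p, which has another sequence (adjusted p = 0.0219; 0.00714 to 0.98 over its alternatives), but carry-over of miR-125a-5p into the miR-125b-5p assay stays open, since the difference of miR-125b-5p was 0.0585 (SE 0.0815) with miR-125a-5p and the mean Cq as covariates, as shared regulation would also give; a biological difference tied to MI or treatment stays open too. With the mean Cq as a covariate, 2 of 100 splits of the samples gave as many miRNAs (3 in the real split, at most 3 in another). In any of 12 fits, 4 of 100 gave 3 or more, and both counts include the real split. However, 6 of the 99 other splits called at least 1 miRNA with that covariate. The 3 miRNAs are also not independent, since miR-125a-5p and miR-125a-3p are arms of the same precursor. The splits covered 12 fits, whereas 29 alternatives were run on the real grouping, so chance is not excluded. Without the covariate, 36 of 100 splits gave as many unadjusted p under 0.05 (3 in the real split, at most 35 in another).

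In the planned test without a covariate 0 miRNAs were called (limma, 3 at an unadjusted p under 0.05), a count that 100 of 100 splits reach by construction, so the splits say nothing about it. In simulated data with 15 of 61 miRNAs changed after normalization, the same test called 28% of log2 changes of 0.5, 76.4% of 1 and 98.8% of 2. In that setting it missed few changes as large as 2, but most changes of 0.5, near the size of the miR-125 differences. Runs with fewer changed miRNAs, where the adjustment is stricter, were not made. Of the other splits, 3 called any miRNA, and the highest count was 31, which points to a structure of the samples: that split had the largest difference in mean Cq of the 99 (1.02 cycles, against -0.00618 in the real split) and called 0 with the mean Cq as a covariate. The lower 14q32 list may reflect correlated assays: its adjusted p was 0.0805 with the correlation estimated, and 29 of 100 splits called as many lists (1 in the real split, at most 2 in another), so chance could not be excluded.

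The 2 assay sets may come from different assay or reagent batches, since miR-126-3p was detected in 27 of 29 samples of set 2 and miR-126-5p, from the same precursor, in 8, and set 2 itself held 20 samples with a miR-7-2-3p Cq of 13.5 to 15.1 and 9 of 17.5 to 18.1. Low RNA input would raise the Cq of set 2, but over the reference miRNAs that follow input it was -1.49 cycles from set 1 (SE 0.501). MI status did not define the sets, as 7 cases and 22 controls lay in set 2. The Cq of miR-133b, miR-7-2-3p, miR-34a-5p and miR-320b hardly followed the other reference miRNAs, with slopes of at most 0.314, and shifted between sets by 1.06 to 3.57 cycles. From set 1 to set 2 the median Cq rose for miR-7-2-3p (11.1 to 14.7) and miR-320b (13.7 to 15.5). The rise of miR-7-2-3p was fixed in advance, since its Cq defined the sets, so it is no evidence on the source. The median Cq fell for miR-133b (18.9 to 17.6) and miR-34a-5p (18.6 to 17.6). So did the Cq of the reference miRNAs that follow input, and the shift of these 2 assays does not set them apart. A product formed without plasma RNA is a candidate source, and no blank reaction was analysed here to test it. A biological source of the sets other than MI status was not tested.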
